A study of Mus musculus with 8 samples.

How the data were processed

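The series holds 8 soleus samples from db/db mice aged 11 weeks, taken 3 weeks after injection of an adeno-associated virus (AAV). In 4 samples the virus carried a short hairpin RNA against Eda (shEda), and in 4 it carried a scrambled hairpin. Groups came from the labels' AAV field and replicate numbers from the titles. The library source is transcriptomic, and libraries were made from poly-A selected RNA with a TruSeq kit, per the labels' protocols.

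The authors deposited 1 table of FPKM (fragments per length of transcript, scaled to the mapped fragments of the library) with 1 value per Ensembl gene and sample. The submitters' processing notes name CASAVA, Cufflinks and the mouse build mm10, with no version or role. The aligner, the gene annotation and the handling of strand are not given in the sources used here. The table had 46406 genes, and all 8 value columns matched a sample title. FPKM from Cufflinks are model estimates, so whole reads could not be recovered, the sequencing depth is unknown, and no count model was used. An FPKM is a share of the library, so a very abundant transcript lowers every other value in that library, and the estimate is unstable for features shorter than a fragment. Exact zeros in the table can be failed estimates. Gapdh was listed at 0 in 1 library and Myh1 in 5, so a value of 0 is described here as listed at 0, without a fold change. No pair of libraries held identical values.

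Gene symbols, coordinates and biotypes were taken from GENCODE release M21 on GRCm38, the assembly that mm10 names, by Ensembl identifier. Of the 46406 identifiers, 45814 matched. Coordinates are 1-based.

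Values entered the tests as deposited, as log2(FPKM + 1). Fold changes are on that scale, which understates the change of genes with low FPKM. Genes with a mean FPKM of at least 1 over all 8 samples were tested, which left 13563 genes, 11276 of them protein-coding. The test was limma 3.58.1 in R 4.3.3, with an empirical Bayes variance trend, no block and Benjamini-Hochberg adjustment at 0.05, two-sided. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures. The level of Eda was tested by an exact two-sided permutation test over the 70 arrangements of the 8 samples. The smallest p this design allows is 0.0286.

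Before the data were examined, 40 gene lists were fixed that cover fibre types, fuel metabolism, signalling, stress responses and markers of other cell types in a dissected muscle. The 37 lists with at least 5 tested members were compared with all other tested genes by camera in limma, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Each list was also tested by camera with an estimated correlation, by fry, and by an exact permutation test of its score. A list score is the mean, over the members with no value at 0, of the log2 deviation from the member's mean over the 8 libraries. Of the 722 gene names in the lists, 8 were not analysed here, and 1 older symbol was updated (Tmem8c to Mymk). Further members had a mean FPKM under 1 and were not tested. This left 10 of 22 for NF-kB targets and inflammatory cytokines and 9 of 22 for cell proliferation.

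Genes were named by a rule fixed before the data were examined. It gave 13 genes of EDA and insulin signalling whatever their values. It added the 12 largest rises and 12 largest falls past the threshold with non-overlapping groups, filled up to 12 per direction by the smallest unadjusted p and given as values that did not pass. It then took up to 4 members with the smallest p from each list that camera called and up to 2 from other lists. Predicted genes, microRNA and small nucleolar RNA genes were to be counted and not named. Mir1957b, the genes singled out in scrambled replicate 1, and the features called only under other settings fall outside the rule and were chosen after their values were seen.

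The gene test was tested on simulated data for this comparison, with 13563 genes drawn at the observed means and spreads and 200 of them changed. It called 70.1% of 67 genes changed 1.5-fold, 89.6% of 67 changed 2-fold and 100.0% of 66 changed 3-fold, with 6 calls among 13363 unchanged genes. Genes were drawn independently, the changed ones had no value at 0, and folds were set on the log2(FPKM + 1) scale. The simulation gave 179 calls in all, which makes the adjusted threshold easier to pass than where few genes are called. These percentages therefore do not give the power in the real data. The list test called a simulated lower shift of 1 list and 0 of 36 unshifted lists, with genes drawn independently, which real genes of a list are not.

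The labels do not say that each sample came from a separate animal, so p-values measure the spread between these samples, which may be technical in part. Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter on low values, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, variance models without the trend and with robust estimation, array weights, a replicate block, and leaving out each of the 8 samples in turn. Chosen after seeing the data were protein-coding genes only, genes with an exact 0 in no library, both of these together without scrambled replicate 1, and the exact permutation test of list scores.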

Results

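Messenger RNA was profiled in the soleus, a postural hind-limb muscle rich in slow fibres, of db/db mice. These mice lack a working leptin receptor and become obese and diabetic. An adeno-associated virus carried a short hairpin RNA aimed at Eda, which encodes ectodysplasin A, a secreted ligand of the tumour necrosis factor family. The series title names EDA made by the liver, obesity and the insulin response of muscle, so the comparison asks which muscle transcripts differ after Eda knockdown. There were 4 samples with the Eda hairpin (shEda) and 4 with a scrambled hairpin. The deposited FPKM summed to between 546102 and 649262 per library, and between 13150 and 13611 genes reached an FPKM of 1. Sequencing depth is unknown. Scrambled replicate 1 stood apart from the rest, with correlations of 0.916 to 0.925 with the other libraries, which reached 0.963 among themselves.

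The targeted gene was measured first. Eda (ENSMUSG00000059327, chromosome X, 99975606 to 100400762 on GRCm38, protein-coding) was near the floor in this muscle, at 1.16 ± 0.211 FPKM in scrambled and 1.07 ± 0.113 in shEda samples (SD, n = 4 each). The 4 scrambled values were 1.23, 1.00, 1.43 and 0.978 and the 4 shEda values 1.21, 0.982, 1.11 and 0.976. The log2 difference of -0.06 was within the spread between samples (exact two-sided permutation test, p = 0.429). The muscle level does not check the labels if the knockdown acts in the liver, which was not analysed here. Eda2r, a receptor of the EDA-A2 form, stood at 7.24 ± 1.62 FPKM in scrambled and 7.10 ± 1.97 in shEda samples (SD, n = 4 each), a log2 difference of -0.04 (exact two-sided permutation test, p = 0.829). Edar, the receptor of the EDA-A1 form, had mean values of 0.265 and 0.179 FPKM, and its adaptor Edaradd was listed at 0 in 7 of the 8 libraries, so neither was tested.

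None of the genes of the insulin response fixed by name passed, and their values overlapped between the groups. The insulin receptor Insr was at 22.5 ± 0.747 FPKM in scrambled and 21.1 ± 1.45 in shEda samples (SD, n = 4 each). Its substrate Irs1 was at 1.97 ± 0.426 and 1.54 ± 0.181 FPKM, and Irs2 at 5.13 ± 2.38 and 5.11 ± 0.861. The kinase Akt2 was at 80.4 ± 9.06 and 91.3 ± 4.79 FPKM, with a log2 fold change of 0.19 (95% confidence interval -0.01 to 0.39). The glucose transporter Slc2a4 was at 260.2 ± 17.3 and 280.1 ± 15.2 FPKM. Mapk8, which encodes the stress kinase JNK1, was at 17.4 ± 1.498 and 15.2 ± 1.85 FPKM, with a log2 fold change of -0.18 (95% confidence interval -0.40 to 0.03). Jun, a target of that kinase, Socs3, an inhibitor of cytokine and insulin signals, and Ppargc1a, a coactivator of mitochondrial genes, had log2 fold changes of 0.06, 0.17 and -0.03. The smallest adjusted p of the 11 tested genes fixed by name was 0.556 (limma).

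**Figure D1:**
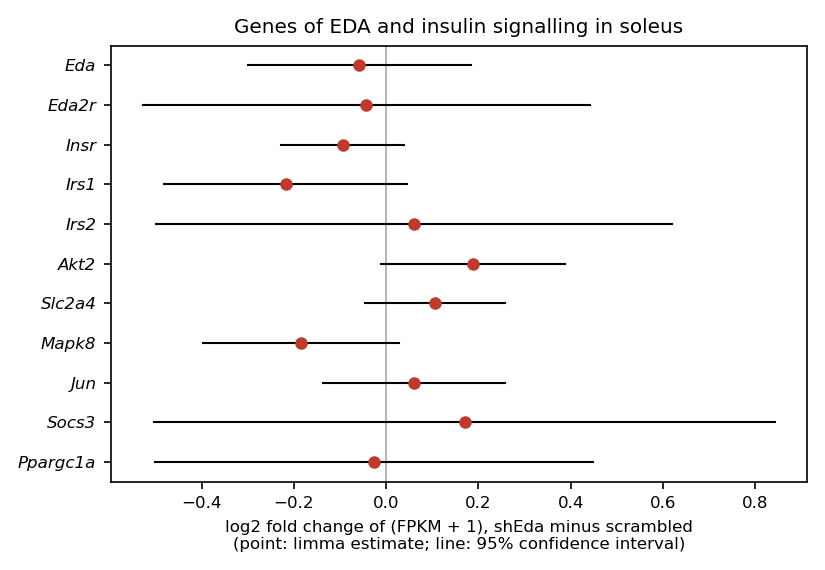
Log2 fold change of (FPKM + 1) between shEda and scrambled soleus (x axis, 4 libraries each) for the 11 tested genes fixed by name (y axis), with points for the limma estimate and lines for the 95% confidence interval. All 11 intervals cross 0, from Irs1 at -0.22 to Akt2 at 0.19.

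Across the transcriptome, 1 of 13563 tested genes passed the threshold (limma, Benjamini-Hochberg), and no protein-coding gene did. The 1 feature was Mir1957b (ENSMUSG00000098410, chromosome 8, 111450200 to 111450322, plus strand), a microRNA gene of 123 nt that lies within an exon of the untranslated region of Wdr59, a gene on the minus strand. It was at 37.3, 16.2, 15.3 and 13.7 FPKM in the scrambled libraries and listed at 0 in all 4 shEda libraries (limma adjusted p = 0.00294). It was chosen after its values were seen, and 49.0% of the values of tested features under 200 nt are listed at 0. The second smallest adjusted p was 0.419. At an unadjusted p under 0.05 there were 1175 genes, 564 higher and 611 lower in shEda, where 678 would fall by chance, and with a library left out the count ran from 662 to 1474. The 4 values of each group did not overlap for 608 genes, or 4.48%, against 2.86% by chance. A replicate block, protein-coding genes only, and genes with no exact 0 each left 0 genes past the threshold, with 863, 1081 and 1251 genes at an unadjusted p under 0.05 (limma).

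The leading differences in single genes were modest and did not pass. In the 12 leading rises the log2 fold change ran from 0.35 to 1.00, and in the 12 leading falls from -0.49 to -0.23, with adjusted p from 0.419 to 0.556 (limma) and no overlap between the groups. Gabrr2, a GABA receptor subunit, was at 1.94 ± 0.613 FPKM in scrambled and 4.93 ± 1.56 in shEda samples (SD, n = 4 each). Complement component C3 was at 3.66 ± 0.651 and 5.99 ± 0.754 FPKM. Gadd45a, a stress-induced gene of growth arrest and muscle atrophy, was at 11.8 ± 1.56 and 16.5 ± 1.55 FPKM. Cox20, an assembly factor of cytochrome c oxidase, was at 9.91 ± 0.724 and 13.9 ± 1.58 FPKM. The other leading rises were Emid1, Arl4d, Acbd4, Ttll5, Cyb5a, the pseudogene Rbx1-ps, and Dynlt1a with its near-identical copy Dynlt1b, whose values are uncertain because reads can be split between copies. Among the falls, the lysosomal sulfatase Arsg was at 3.47 ± 0.265 and 2.21 ± 0.129 FPKM. Fzd9, a Wnt receptor, was at 77.6 ± 10.8 and 56.3 ± 2.81 FPKM, and Akap6, an anchor of protein kinase A, at 12.7 ± 0.764 and 9.002 ± 1.34. Shc1, an adaptor of receptor tyrosine kinases, was at 15.4 ± 0.337 and 13.0 ± 0.675 FPKM. The remaining falls were Ccdc136, Rab11fip3, Slc12a4, Trim7, Spats2l, Il17d, Sbf2 and the pseudogene Cdv3-ps.

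Most genes of slow, oxidative fibres had lower values in shEda soleus, in a list called only with the preset correlation. Of 12 slow fibre genes 11 had lower values, with a median log2 fold change of -0.51 (camera adjusted p = 1.18e-07). With an estimated correlation the call was lost (adjusted p = 0.907, and 0.0808 before adjustment). None passed over all genes, and 8 of 12 passed adjusted over the list alone. The estimated correlation between members was 0.715, so these 8 do not count as separate results. The slow regulatory light chain Myl2 was at 2753 ± 389.6 FPKM in scrambled and 2077 ± 229 in shEda samples (SD, n = 4 each), and the calcium-binding protein Casq2 at 164 ± 31.7 and 112 ± 20.6. Slow troponin C, Tnnc1, was at 2045 ± 428 and 1445 ± 165 FPKM, and slow troponin I, Tnni1, at 1425 ± 313 and 987 ± 136. The mean slow fibre score was 0.24 ± 0.28 in scrambled and -0.24 ± 0.24 in shEda libraries (SD, n = 4 each; exact two-sided permutation p = 0.0286, the smallest this design allows, and 0.470 adjusted over 37 lists). The groups barely parted, with a lowest scrambled score of -0.0486 and a highest shEda score of -0.0505. Scrambled replicate 1 had the highest slow fibre score, 0.59. Without it the median log2 fold change was -0.38 (camera adjusted p = 2.68e-07) and the exact permutation p of the score was 0.114.

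Most genes of fast fibres had higher values in shEda, in a list called only with the preset correlation. Of 14 fast fibre genes 12 had higher values, with a median log2 fold change of 0.31 (camera adjusted p = 0.000798). With an estimated correlation this call was lost as well (adjusted p = 0.907). No member passed, either over all genes or adjusted over the list alone. The scores overlapped between the groups (exact permutation p = 0.114). The kinase Mylk2 was at 207 ± 26.5 FPKM in scrambled and 276 ± 35.4 in shEda samples (SD, n = 4 each). Fast troponin I, Tnni2, was at 2827 ± 378 and 3374 ± 312 FPKM, and the fast calcium pump Atp2a1 at 2649 ± 534 and 3301 ± 225. Scrambled replicate 1 had a fast fibre score of -1.43, far under the other 7 libraries, and without it the median log2 fold change was 0.18 (camera adjusted p = 0.000832). Myh1 was listed at 0 in 5 libraries.

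**Figure D2:**
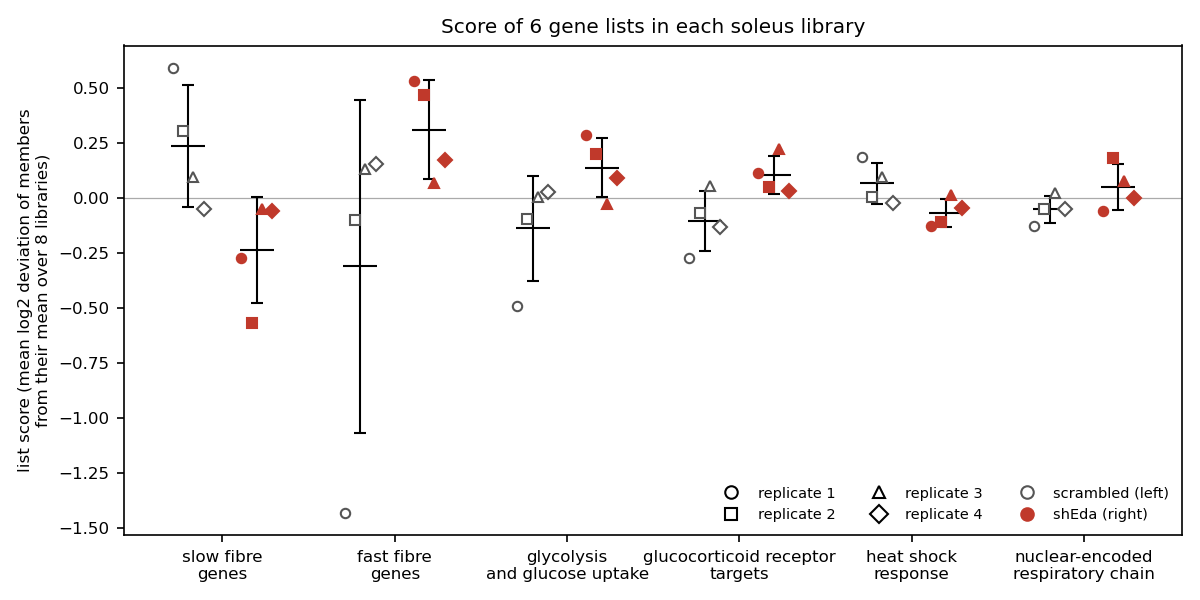
Scores of 6 gene lists (x axis) in each of the 8 soleus libraries, as the mean log2 deviation of a list's members from their mean over all libraries (y axis). Open grey symbols are scrambled and filled red symbols shEda libraries, the symbol shape gives the replicate, and black bars are the mean and SD of 4. The slow fibre scores run from -0.0486 to 0.59 in scrambled and from -0.57 to -0.0505 in shEda libraries, and scrambled replicate 1 has a fast fibre score of -1.43.

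Most genes of glucose breakdown and of the mitochondrial respiratory chain had higher values by small amounts, in lists called only with the preset correlation. Of 18 genes of glycolysis and glucose uptake 13 had higher values (median log2 fold change 0.25, camera adjusted p = 0.00681, and adjusted p = 0.907 with an estimated correlation). Lactate dehydrogenase Ldha was at 692 ± 98.9 FPKM in scrambled and 889 ± 136 in shEda samples (SD, n = 4 each), and muscle enolase Eno3 at 1121 ± 256 and 1569 ± 289.7. Gapdh is among the 5 lower only because it was listed at 0 in shEda replicate 1, and with such genes left out the list kept its call. All 38 nuclear-encoded genes of the respiratory chain had higher values, with a median of only 0.10 (camera adjusted p = 8.80e-07, and adjusted p = 0.907 with an estimated correlation). That correlation was 0.805, so the 38 genes do not count as separate results. The complex I subunit Ndufs7 was at 458 ± 39.1 and 527 ± 42.9 FPKM and Ndufs8, another, at 119 ± 8.21 and 136 ± 12.2. Of 13 mitochondrially encoded genes 11 were higher (median 0.09, camera adjusted p = 0.0147, and adjusted p = 0.907 with an estimated correlation), among them mt-Nd3 at 1393 ± 39.5 and 1605 ± 155 FPKM. Of 21 genes of the citric acid cycle and pyruvate dehydrogenase 18 were higher (median 0.08, camera adjusted p = 0.0147, and adjusted p = 0.907 with an estimated correlation). Idh3a was at 184 ± 27.5 and 224 ± 20.7 FPKM, and Pdk1, an inhibitor of pyruvate dehydrogenase, at 53.4 ± 5.98 and 44.5 ± 5.97. In contrast, 30 of 33 genes of fatty acid uptake and oxidation had lower values (median -0.07, camera adjusted p = 0.0220, and adjusted p = 0.958 with an estimated correlation). Lipoprotein lipase Lpl was at 484 ± 16.4 and 425 ± 79.5 FPKM and Fabp3 at 1587 ± 72.8 and 1410 ± 273. No member of these 5 lists passed, over all genes or adjusted over the list alone. The scores of all 5 overlapped between the groups. The exact permutation p was 0.0857 for glycolysis, 0.2 for the respiratory chain and 0.314 for mitochondrially encoded genes. It was 0.286 for the citric acid cycle and 0.571 for fatty acid oxidation. The median of the respiratory chain genes was 0.05 without shEda replicate 2 and 0.06 under quantile normalization, still called. The glycolysis score was lowest in scrambled replicate 1, at -0.49, and without that library the median was 0.17 (camera adjusted p = 0.0263).

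The last 3 of these lists each lost their call when any of several libraries was left out, not always with a smaller median. The mitochondrially encoded genes lost theirs without scrambled replicate 2 or 4 or shEda replicate 2 (camera adjusted p = 0.0548, 0.101 and 0.255, with medians of 0.09, 0.08 and 0.04) and under quantile normalization (0.665, median 0.02). The citric acid cycle genes lost theirs without scrambled replicate 1 or shEda replicate 2, 3 or 4 (camera adjusted p = 0.142, 0.247, 0.0870 and 0.0622, with medians of 0.05, 0.06, 0.09 and 0.09) and under quantile normalization (0.156, median 0.05). Fatty acid oxidation lost its call without scrambled replicate 2 or 3 or shEda replicate 4 (camera adjusted p = 0.0659, 0.0764 and 0.160, with medians of -0.06, -0.06 and -0.06), under array weights (0.121, median -0.04), and without shEda replicate 1, where the median turned to 0.02 (0.607).

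Most targets of the glucocorticoid receptor and most genes of muscle atrophy had higher values, in lists called only with the preset correlation. Of 18 glucocorticoid receptor targets 15 had higher values (median log2 fold change 0.16, camera adjusted p = 0.00317, and adjusted p = 0.907 with an estimated correlation). Glutamine synthetase Glul was at 85.7 ± 15.2 FPKM in scrambled and 113 ± 6.54 in shEda samples (SD, n = 4 each), Arrdc2 at 33.8 ± 14.1 and 57.6 ± 7.68, and Tsc22d3, a glucocorticoid-induced leucine zipper, at 92.6 ± 10.1 and 112 ± 13.3. Of 21 atrophy and FOXO target genes 15 had higher values (median 0.11, camera adjusted p = 0.0220, and adjusted p = 0.907 with an estimated correlation), and 1, Gadd45a, passed adjusted over the list alone. The muscle ubiquitin ligases Trim63 and Fbxo32 were at 169 ± 53.8 and 236 ± 29.5 FPKM, and at 93.3 ± 22.4 and 123 ± 10.5 FPKM. Ddit4, an inhibitor of mTOR signalling that both lists hold, was at 66.1 ± 14.4 and 96.9 ± 20.3 FPKM. The scores of both lists overlapped between the groups (exact permutation p = 0.0857 for each). The atrophy list lost its call without scrambled replicate 1, 2 or 4 or shEda replicate 3 (camera adjusted p = 0.0756, 0.0513, 0.0548 and 0.167), where the median was 0.11, 0.11, 0.07 and 0.07.

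Most chaperone genes and most genes of insulin signalling had lower values, in lists called only with the preset correlation. Of 16 heat shock genes 14 had lower values (median log2 fold change -0.11, camera adjusted p = 0.00317, and adjusted p = 0.907 with an estimated correlation). The small chaperone Cryab was at 1211 ± 167 FPKM in scrambled and 1044 ± 49.9 in shEda samples (SD, n = 4 each), and Hspb8 at 198 ± 16.2 and 175 ± 15.6. Of 28 insulin signalling genes 18 had lower values (median -0.10, camera adjusted p = 0.0220, and adjusted p = 0.907 with an estimated correlation). The members with the smallest p were Pten, a brake on the pathway, at 8.90 ± 0.346 and 7.73 ± 0.566 FPKM, Rptor, a part of mTOR complex 1, at 15.1 ± 0.995 and 13.0 ± 1.34, and the kinase Akt1 at 47.4 ± 3.33 and 41.5 ± 3.91. No member of either list passed, over all genes or adjusted over the list alone. The scores of both lists overlapped between the groups (exact permutation p = 0.0857 for heat shock and 0.257 for insulin signalling). The highest insulin signalling score, 0.06, was that of shEda replicate 4. The insulin signalling list lost its call without scrambled replicate 2, 3 or 4 or shEda replicate 1 (camera adjusted p = 0.0513, 0.0764, 0.0509 and 0.178), where the median was -0.11, -0.07, -0.11 and -0.04.

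The other 26 lists did not pass, with camera adjusted p from 0.0841 to 0.975. Of 10 tested genes of the EDA receptor pathway 7 had lower values (median log2 fold change -0.03, adjusted p = 0.490), with the kinase Chuk at 24.2 ± 2.97 FPKM in scrambled and 20.3 ± 2.27 in shEda samples (SD, n = 4 each). NF-kB targets and inflammatory cytokines (10 of 22 members tested, median 0.03, camera adjusted p = 0.900) and AP-1 and immediate early genes (median 0.09, camera adjusted p = 0.158) were also not called. The closest was glycogen metabolism (median 0.29, 10 of 14 higher, camera adjusted p = 0.0841), with the phosphorylase kinase subunit Phka1 at 51.6 ± 14.9 and 73.8 ± 12.4 FPKM. Without scrambled replicate 1 the glycogen median was 0.14 (camera adjusted p = 0.276), while without scrambled replicate 3 or shEda replicate 3 or at a mean FPKM of at least 5 the list was called (0.0284, 0.0411 and 0.0362). With an estimated correlation and all 8 libraries the glycogen list had a camera adjusted p of 0.907. Satellite cell and regeneration genes had a median of -0.11 (camera adjusted p = 0.0900). Without scrambled replicate 1 it was -0.02 (0.815), and without scrambled replicate 2 or 4 or shEda replicate 1 the list was called (camera adjusted p = 0.0451, 0.0408 and 0.0366). With an estimated correlation and all 8 libraries the satellite cell list had a camera adjusted p of 0.907. Denervation and neuromuscular junction genes had a median of -0.13 (camera adjusted p = 0.140, 0.0487 without scrambled replicate 3, and 0.907 with an estimated correlation and all 8 libraries). In this list Gadd45a passed adjusted over the list alone. Among markers of other cells, the median was -0.08 for fibroblast and matrix genes, 0.19 for tendon, 0.01 for endothelium, -0.03 for macrophages and 0.20 for red blood cells, with camera adjusted p from 0.846 to 0.975. For macrophages the test statistic was of the opposite sign to the median. Scrambled replicate 1 had the highest macrophage score, 0.88, and without it the macrophage list was called higher in shEda with the preset correlation (median 0.30, camera adjusted p = 9.01e-05), as were the AP-1 genes (median 0.13, camera adjusted p = 0.0204, and 0.0497 under array weights). No test with an estimated correlation was run in these settings, and with all 8 libraries it gave adjusted p = 0.988 and 0.907. Lists of lymphocytes, brown adipocytes and hepatocytes had under 5 tested members.

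The 11 calls, 7 higher and 4 lower, all came from camera with its preset correlation of 0.01. In that test the other splits of the 8 libraries into 4 and 4 gave a median of 10 called lists. None of the 37 lists was called with an estimated correlation (smallest adjusted p = 0.907, with 0 lists at an unadjusted p under 0.05), by fry (smallest adjusted p = 0.522, with 3 lists) or by the exact permutation test of list scores (smallest adjusted p = 0.470, with 1 list). With a smallest possible p of 0.0286, the exact test could not call a list on its own after adjustment over 37 lists. Its lack of calls therefore decides nothing. The 3 lists by fry were slow fibre genes, heat shock and glucocorticoid receptor targets. Many lists share the adjusted p of 0.907 through the adjustment. Before it, camera with an estimated correlation gave p from 0.0771 for heat shock to 0.547 for fatty acid oxidation among the 11 lists. The estimated correlation between members of the 11 lists ran from 0.116 for insulin signalling, through 0.715 for slow fibre genes, to 0.805 for the respiratory chain.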

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

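The tests of the slow fibre score over other splits and without scrambled replicate 1, the test of fibre content in that library, and the form of the test of zeros given here were chosen only after the result was seen. The other tests were written down before their values were seen.

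In each group of 4 libraries, the library farthest from the rest was compared with the group's range, for 37 list scores, 104 genes and 5 library measures. Of 292 groups, 23 held a library far from the others. Chance marks about 1 in 20, which holds only for items not picked for their values. Without 10 items picked after their values were seen, among them Selenow and Itgam, 19 of 272 groups did. At 1 in 20 this would be 13.6, but many of the genes left were named for a small p, so that rate need not hold. Scrambled replicate 1 was the library in 8 of the 19. It had 27394 FPKM of Selenow, a small selenoprotein abundant in muscle, against 2001 to 3032 in the other scrambled libraries, and this gene made up 4.22% of its total against 1.97% to 2.04% for the top gene of the others. Its fast fibre score was -1.43 against -0.10 to 0.16, its satellite cell score 0.47 against -0.10 to -0.01, and its cell proliferation score 0.25 against -0.03 to -0.02. It held 2.60 FPKM of Irs1 against 1.71 to 1.86, 3.85 of Socs3 against 0.967 to 1.42, 13.8 of Pdpk1 against 11.8 to 12.1, 4.29 of the myeloid integrin Itgam against 0.525 to 0.812, 48.6 of Cd74, a gene of antigen-presenting cells, against 6.13 to 9.74, 43.1 of Cry2 against 37.6 to 38.5, and 37.3 of Mir1957b against 13.7 to 16.2. In the other scrambled libraries, Jun was at 37.5 FPKM in replicate 3, Dynlt1a at 26.8 in replicate 2 and Ttll5 at 1.51 in replicate 4. Replicate 1 of the shEda group had an AP-1 score of 0.39 against -0.10 to -0.03, a p53 target score of 0.14, 18.2 FPKM of Klf6 and 131 of Tsc22d3. Replicate 2 of that group had a cell proliferation score of -0.17, an ER stress score of -0.0237 and 1835 FPKM of mt-Nd3, and replicate 4 had 25.2 FPKM of the liver gene Apoa2 against 0.665 to 1.36.

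The lower slow fibre genes in shEda were weighed first. For this list alone, only 1 of 35 splits of the 8 libraries, the real one, gave a score difference as large. That is the exact permutation p of 0.0286 given above in another form, and not a further test. The margin was narrow (0.472, against 0.471 for the highest other split), and this was the leading list of 37. For the number of called lists chance cannot be excluded, since 13 of 35 splits gave at least as many as the real 11. The other splits gave a median of 10 called lists and at most 17. With the preset correlation, arbitrary groupings thus gave about as many calls as the real one. Without scrambled replicate 1 the difference kept its sign, at -0.35 with a standard error of 0.16. The difference stayed beyond the limit written for this test by more than its standard error, which argues against that library as the whole source. What remained was not set apart from chance (exact permutation p = 0.114). Other contents of the piece cannot be told apart as a source, because the lowest change among 4 lists of other cells, -0.0672 for fibroblast and matrix genes, had a standard error of 0.24 against a limit of -0.16, and tendon and macrophage genes were as variable, whereas endothelial genes changed by 0.0039 with a standard error of 0.042. These 4 lists are not markers of muscle fibres, so they could not show a difference in the fibre types of the dissected piece. A lower slow-fibre program after Eda knockdown, and differences in fibre type between animals or dissected pieces, remain open as hypotheses.

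The second pattern is scrambled replicate 1, whose genes of the fastest fibres, chosen after their values were seen, were far down. Myh4 was at 93.1 FPKM against 1213 to 1846 in the other scrambled libraries, Actn3 at 40.4 against 519 to 809, Mybpc2 at 14.8 against 241 to 428, Pvalb at 98.7 against 972 to 1279, and the tendon gene Tnmd at 1.60 against 5.87 to 14.4. Recovery of transcripts by length argues poorly for this, since the median deviation from the other 3 scrambled libraries was -0.46 for fast fibre genes and -1.43 for tendon genes, while the 95% intervals of 10000 random lists of matched length had lower bounds of -0.17 and -0.19. A piece of muscle with less fast-fibre tissue is a candidate explanation, since slow fibre genes deviated by 0.50 and glycolysis genes by -0.37, but it leaves Selenow and the higher macrophage genes (1.17) and red blood cell genes (1.78) aside. The groups give no biological explanation for a single library, beyond the content of the dissected piece, and no other was tested.

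The third pattern is the call of Mir1957b. Estimation of short features could give it, since 49.0% of values were listed at 0 in the 515 tested features under 200 nt and 0.0337% in the 12984 longer ones. Zeros that line up with the groups by chance remain open too, since among 35 other distinct profiles of short features listed at 0 in exactly 4 libraries, all 4 zeros fell in 1 group in 1, against 1 expected (one-sided exact binomial p = 0.637, and 0.124 in the form fixed first, which gave 3 of 43 with Mir1957b and each of the identical features counted). For the number of genes past the threshold chance cannot be excluded, since 15 of 35 splits gave at least the real 1, and the highest other split gave 6. Other groupings of the libraries thus also gave calls, and which features they called was not examined. At an unadjusted p under 0.05, 3 of 35 splits gave at least the real 1175 genes, with 1806 in the highest other. The feature lies within an exon of Wdr59 on the other strand, and the handling of strand is not given. Reads there could therefore come from either gene, and the call cannot be assigned to the microRNA. A change of the microRNA precursor itself was not tested and stays open.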

How the results depend on the processing

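The settings with short features or exact zeros removed, and the exact permutation test of list scores, were chosen only after the results were seen. The number of genes past the threshold was 1 as reported. It was 3 with a pseudocount of 0.1 (Mir1957b and the microRNA genes Gm24302 and Gm24643, which hold identical values), 2 with no filter on low values (Mir1957b and Gm11802, at under 0.1 FPKM), and 1 to 3 with each library left out, with Mir1957b among them each time (662 to 1474 genes at an unadjusted p under 0.05). It was 0 with protein-coding genes only, 0 with genes that have an exact 0 in no library, and 0 for both together without scrambled replicate 1 (1081, 1251 and 702 genes at an unadjusted p under 0.05, limma), because Mir1957b was then not tested.

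With the replicate block it was 0 (863 genes at an unadjusted p under 0.05, limma), as Mir1957b had an adjusted p of 0.113, against 1.66e-06 to 0.0333 with a library left out. The values gave no sign that the numbers in the titles pair the samples, though 4 libraries per group cannot exclude it. The correlations of same-numbered deviations were 0.01, -0.03, 0.05 and -0.04, and only scrambled replicate 3 correlated best with its own number. The block called 11 lists, the same 11.

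The Eda difference kept its sign, from -0.10 to -0.00070 with a library left out and from -0.10 to -0.03 in the other settings, with no call in any. At a mean FPKM of at least 5 Eda was not tested.

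The 11 list calls fell to 0 with an estimated correlation, 0 by fry and 0 by the exact permutation test. The exact test could hardly call a list after adjustment, given the smallest p that 70 arrangements allow. In the other settings 8 to 12 lists were called, 8 to 11 of them with a library left out. The split was 7 higher and 4 lower as reported and 5 and 5 under quantile normalization, where the ribosomal protein list was called lower and 2 lists lost their call. Of the 11 lists, 6 were called in all 21 other camera settings with the preset correlation (slow fibre, fast fibre, respiratory chain, heat shock, glucocorticoid targets, glycolysis). Fatty acid oxidation turned from -0.07 to 0.0220 without shEda replicate 1, and ran from -0.149 to 0.0220 with a library left out. Scaling moved the median of all genes by less than 0.01. The cause of these changes was not tested. Of 2014 values of 97 named genes under other settings, 14 changed sign, none of them called. Unknown depth limits what can be said of genes near the floor such as Eda and Edar.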

Other observations

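Some genes outside the called lists had non-overlapping groups at a small unadjusted p without passing over all genes, in a family of 13563 tests. Chac1, a glutathione-degrading enzyme induced by the integrated stress response, was at 3.45, 5.04, 6.67 and 6.74 FPKM in scrambled and 19.3, 10.3, 16.8 and 8.34 in shEda libraries, with a log2 fold change of 1.14 (95% confidence interval 0.50 to 1.79). The chaperone Pdia6 of the same list was lower, at 33.1 ± 4.73 against 26.4 ± 1.20 FPKM (SD, n = 4 each), and the 22 tested genes of that list split evenly, with 11 higher and 11 lower (camera adjusted p = 0.897, median -0.01, mean 0.04). The clock repressor Cry2 was at 39.2 ± 2.60 and 33.2 ± 1.13 FPKM (SD, n = 4 each), while the clock list as a whole was not called (camera adjusted p = 0.641). The nicotinic receptor subunit Chrna1 was at 20.9 ± 4.48 and 15.2 ± 1.18 FPKM (SD, n = 4 each). The nuclear receptors Esrrg and Esrrb of oxidative metabolism were at 31.7 ± 3.22 and 24.1 ± 6.47, and at 17.2 ± 3.04 and 13.0 ± 2.54 FPKM, with overlapping groups. Of the 15 tested genes of their list 10 were lower (median -0.05, camera adjusted p = 0.242, and 0.0412 without shEda replicate 4). With an estimated correlation and all 8 libraries the adjusted p was 0.907, and none was run without that library.

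Transcripts of other tissues varied widely between libraries. The immunoglobulin gene Ighm was at 1.06 ± 0.352 FPKM in scrambled and 3.26 ± 1.27 in shEda samples (SD, n = 4 each), with no overlap between the groups and a limma adjusted p of 0.556. The haemoglobin gene Hba-a1 ran from 133 to 544 FPKM in scrambled and from 66.9 to 848 in shEda libraries. The liver apolipoprotein gene Apoa2 was at 25.2 FPKM in shEda replicate 4 and at most 1.56 in the other 7 libraries, and the liver gene Cyp2e1 was at 0.452 ± 0.198 and 2.33 ± 1.98 FPKM (SD, n = 4 each) with overlapping groups. The hepatocyte list, tested only with no filter on low values, was then called higher in shEda with the preset correlation (median log2 fold change 0.39, camera adjusted p = 0.0273), and no test with an estimated correlation was run for it. The lymphocyte and brown adipocyte lists, tested only in the same way, were not called (camera adjusted p = 0.924 and 0.888).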
